A study of Mus musculus with 2 samples.

How the data were processed

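Chromatin accessibility was measured by DNase-seq, in which the enzyme DNase I cuts DNA in nuclei where it is not covered by nucleosomes and the cut ends are sequenced. The tissue was hippocampus (the labels name a layer of it without saying which) from male mice aged 2 months of the strain B6CASTF1/J, a first-generation cross of B6 and CAST mice. The series held 1 group of 2 samples. Per the labels these were biological replicates 1 and 2 from separate biosamples with the same donor entry. No label said whether they came from separate animals, so differences between them measure a spread that may be partly technical. No treatment or other tissue was present, so no comparison between groups was made.

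The authors deposited, for each sample separately, 2 lists of peaks, 1 list of footprints (short protected stretches inside open chromatin) and a file of false discovery rates (FDR) per interval, all on assembly mm10 per the labels. The aligner, the peak and footprint callers and their thresholds are not given in the sources used here. The height of each deposited peak was read as a signal value. Within each sample all heights below 500 steps were whole multiples of 1 step, within a tolerance of 0.02 steps, and this step was 0.00535 in replicate 1 and 0.0108 in replicate 2. If 1 step is 1 read or cut and heights were scaled as in CPM, the reciprocals of the steps, 187 and 93.0, are the depths in M reads or cuts, a ratio of 2.01. This reading of the steps is an inference from the values, the depth itself is not given in the sources used here, and comparisons of height between replicates rest on it. The deposited FDR was read as a q-value per interval. Its lowest value inside a peak reached at most 0.0499 in the longer list of either replicate, and at most 0.00123 in replicate 1 and 0.000995 in replicate 2 in the shorter list, called the FDR 0.001 list below. Footprints carried the constant 0.01 in the column where a p-value per footprint would stand, so they were used by position only. Both parental alleles were placed on 1 reference assembly, so heights pool the alleles.

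The longer list of each sample was the main list. A shared peak was the intersection of overlapping peaks of both replicates (at least 1 bp), with intersections that overlapped merged. Its height in a replicate was the highest value of that replicate's peaks over it. Annotation came from GENCODE M21 (21853 protein-coding genes) on GRCm38, the same assembly as mm10. The last peak on each of the 19 autosomes, X and Y ended within the length of the GRCm38 chromosome, and other sequences were left out. A start site was the first base of any protein-coding transcript. A promoter was open where a shared peak overlapped 500 bp on either side of a start site, and a distal peak lay over 2500 bp from every start site. Closed means only that no shared peak was found there, since a promoter open in few cells of the tissue may give none. Peaks were classed in the order start site, exon, intron and intergenic, and compared with 100 shuffles of the same regions on the same chromosome outside gaps. These classes used protein-coding genes only, so other annotated genes outside them counted as intergenic. For the 10 strongest distal peaks, genes and exons of every type were used. The 24 gene lists, 24 motif sequences, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took from each list the 3 open members highest by mean height, up to 3 members without a peak in either replicate in alphabetical order, and members open in 1 replicate only where these were at most 5. It also took the 10 genes (among those of at least 10 kb) and the 10 windows of 100 kb (step 50 kb) densest in shared peaks, and the 10 strongest distal peaks. Genes outside the rule are identified where they appear, and some genes that the rule took are not reported here. A list gene absent under its own symbol was matched through its synonym, as Nov was to Ccn3. Genes with many start sites had more chance of an open promoter.

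Open promoters of each list were compared with all other protein-coding genes by two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 24 lists. Distal density was the number of distal shared peaks per 100 kb of gene body plus 10 kb on each side. The median of a list was placed among 10000 random lists matched on length in 20 bins, with two-sided p-values adjusted over the lists. Genes, regions and footprints are not independent replicates, so all p-values describe these 2 libraries. Motifs were matched exactly on either strand in footprints extended by 10 bp on each side. The controls were equally wide segments 100 bp away in the same peak, which required room in the peak and left 151846 of 255536 footprints in replicate 1 and 81366 of 111355 in replicate 2. Footprints in narrow peaks were therefore under-represented in that comparison. In peaks of about the median width (180 and 200 bp) footprints near the centre were also left out. Those kept there lay nearer an edge, with the control segment toward the opposite edge. Its Fisher's exact tests did not use the pairing of each footprint with its control segment. Shares of peaks and footprints carry exact 95% binomial intervals, which cover counting error only. Alternatives covered the shorter peak lists, stricter and equal-length lists, 50% reciprocal overlap, promoter windows of 200 and 2000 bp, GC-matched lists, a 50 kb flank, other motif controls and each replicate alone. Mean distal density (also with the FDR 0.001 lists), equal deciles of height and genes without another start within 1000 bp were added after seeing the data.

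The functions were tested on simulated data. For promoter lists, 3 lists were set to 95% open and 3 to 10% against 57% elsewhere, over 21853 genes and 100 data sets. Raised lists were called in 79% (pan-neuronal), 84% (excitatory neuron) and 57% (CA1, 10 genes) of data sets, lowered lists in 91% (muscle), 98% (blood) and 91% (germ cell), and unchanged lists in 0.611%. Lists of about 10 genes could therefore miss a difference of that size. Of simulated lists with 4 times the distal density, 80% were called and 0% of unchanged lists, over 10 data sets. Counts there were drawn independently for each gene at a common base rate. Real distal sites cluster and are shared between neighbouring genes, so these rates may not hold for the real data. All 7000 planted overlaps among 20000 regions were found. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.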

Results

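DNase-seq of adult mouse hippocampus, the forebrain region of the CA1 to CA3 pyramidal fields and the dentate gyrus, gave 132685 peaks in replicate 1 and 59880 in replicate 2. These covered 24.0 and 13.3 Mb, with median widths of 180 and 200 bp. Replicate 1 also held 255536 footprints against 111355 in replicate 2, with median lengths of 9 and 8 bp. The median peak height was 0.663 in replicate 1 and 0.936 in replicate 2, in the authors' signal units, whose scaling is not given in the sources used here. Heights below are given for replicate 1 first and replicate 2 second.

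Strong sites were found in both replicates, while weak sites were often found in a single replicate, more of them in replicate 1. Of the replicate 2 peaks, 81.8% (95% interval 81.5 to 82.1) overlapped a peak of replicate 1, against a mean of 2.18% after shuffling. Of the replicate 1 peaks, 38.0% (37.8 to 38.3) overlapped a peak of replicate 2, against 0.997%. The share of replicate 1 peaks found in replicate 2 went from 3.30% in the lowest decile of height to 97.7% in the highest. For replicate 2 peaks found in replicate 1 it went from 40.4% to 99.4%. Across the 50780 shared peaks, log10 heights correlated with a Pearson r of 0.82 and Spearman's rho was 0.796. These are correlations across regions, which are not independent replicates. Median heights at shared peaks were 1.48 and 1.09, and the median log2 ratio of replicate 2 to replicate 1 was -0.48. With lists of equal length the overlaps were 65.4% and 64.6%, and requiring 50% reciprocal overlap left 32100 shared peaks.

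**Figure D1:**
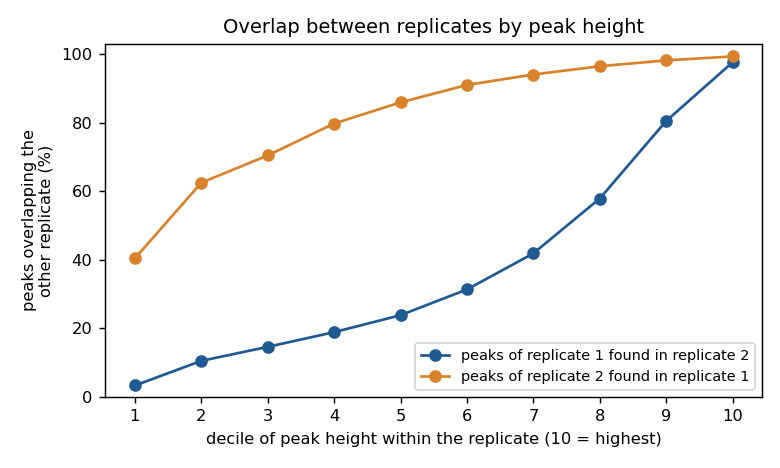
Share of peaks overlapping a peak of the other replicate (vertical axis, percent) in each decile of peak height within a replicate (horizontal axis), with 1 line per replicate. In the highest decile 97.7% of replicate 1 peaks and 99.4% of replicate 2 peaks overlapped the other replicate.

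Promoters took up far more of the shared accessible sites than their share of the genome. Of the shared peaks, 34.2% lay within 500 bp of a protein-coding start site, against 1.61% after shuffling, a 21.2-fold excess. Exons held 6.84% against 4.56%. Introns held 25.9% against 35.7%, and intergenic sequence 33.1% against 58.1%. All 4 shares lay outside the range of the 100 shuffles. Distal sites, over 2500 bp from any start, made up 55.5% of shared peaks. Median heights at promoter peaks were 2.57 and 1.90, and at distal peaks 1.27 and 0.871. In replicate 1 alone, with its many weaker peaks, 17.9% of peaks lay at start sites, against 31.9% in replicate 2.

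Promoters of genes used by every cell, by neurons and by excitatory synapses were open more often than those of other genes. Of all 21853 protein-coding genes, 57.1% had an open promoter in both replicates. All 15 housekeeping genes did (adjusted p = 0.000864, Fisher's exact test), led by the ribosomal protein gene Rplp0 (heights 10.3 and 5.41), the actin gene Actb (9.88 and 5.11) and the elongation factor gene Eef2 (9.47 and 4.30). All 16 immediate-early genes, which neurons transcribe within minutes of stimulation, were open (adjusted p = 0.000538, exact test). Their strongest promoters were Jun (11.4 and 4.27), Egr1 (9.36 and 5.09) and Homer1 (7.70 and 4.73). Of 19 genes for glutamate receptors and their scaffold, 18 were open (adjusted p = 0.00157, exact test), led by the receptor subunit genes Gria2 (5.35 and 2.67), Grin1 (4.45 and 2.28) and Grik2 (3.48 and 3.09). Shank1 had a peak in replicate 1 only. Of 14 excitatory neuron genes, 13 were open (adjusted p = 0.0102, exact test), led by Zbtb18 (5.63 and 3.33), the kinase gene Camk2a (3.67 and 2.73) and Nptx1 (3.36 and 3.001). The vesicular glutamate transporter gene Slc17a7 had a peak of height 1.32 in replicate 1 only. Of 15 pan-neuronal genes, 13 were open (adjusted p = 0.0466, exact test), led by Tubb3 (4.20 and 2.75), Syt1 (3.52 and 2.72) and Map2 (3.55 and 2.65). Gap43 was open in replicate 1 only, and the peaks of the replicates at Eno2 did not overlap. The pan-neuronal list did not pass against random lists matched on promoter GC content (adjusted p = 0.0948, permutation test), in the FDR 0.001 lists (0.16), with 50% reciprocal overlap (0.0735) or with a promoter window of 2000 bp (0.0588, exact tests), and the immediate-early list did not against GC-matched lists (0.0704, permutation test) or with reciprocal overlap (0.127, exact test). The excitatory neuron list did not pass in the FDR 0.001 lists, with reciprocal overlap or with a window of 200 bp (adjusted p = 0.464, 0.504 and 0.14, exact tests), nor the glutamate receptor list in the FDR 0.001 lists or among the top 50% of each replicate's peaks (adjusted p = 0.214 and 0.0836, exact tests).

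**Figure D2:**
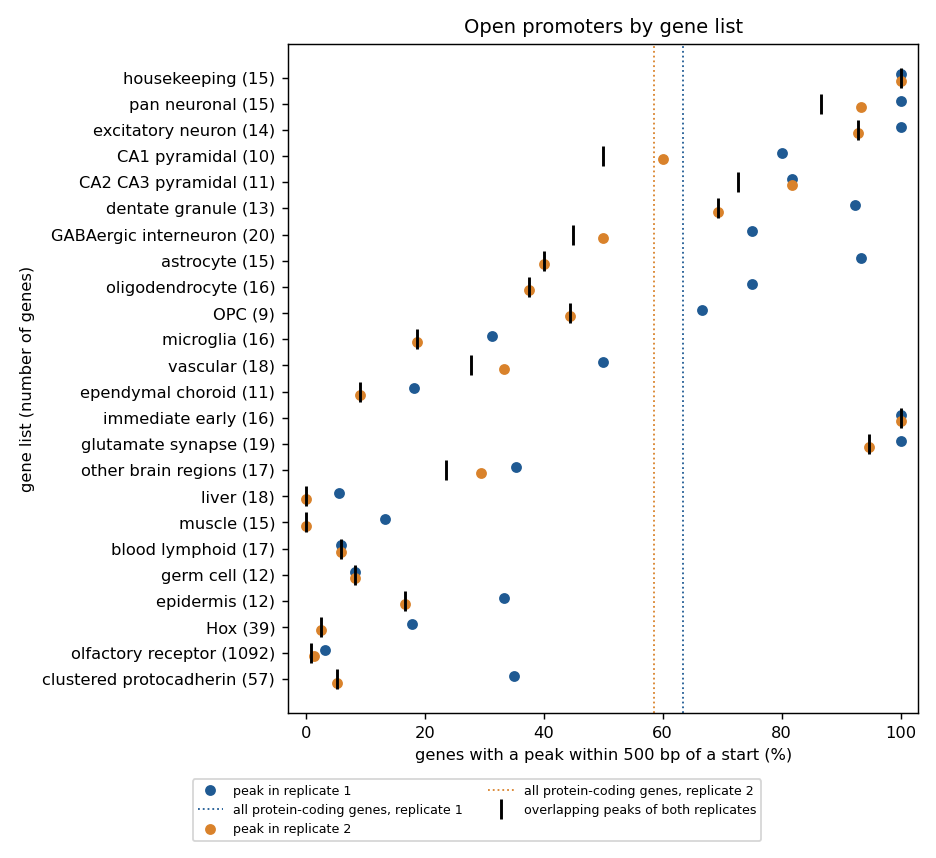
Share of genes in each list with a peak within 500 bp of a start site (horizontal axis, percent), for replicate 1, replicate 2 and overlapping peaks of both, with the number of genes in parentheses and dotted lines for all protein-coding genes. Housekeeping and immediate-early lists reached 100% in both replicates, and liver and muscle lists 0% for overlapping peaks.

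Markers of single hippocampal cell types lay between these extremes, and none of the CA field, dentate or interneuron lists passed the test. For CA1 pyramidal cells 5 of 10 genes were open (adjusted p = 0.753, exact test), led by Wfs1 (5.66 and 2.16), Man1a (4.09 and 2.54) and Cntnap5a (0.813 and 1.23). Dcn, Fibcd1 and Mpped1 had a peak in replicate 1 only, Pou3f1 in replicate 2 only, and Lefty1 in neither. For CA2 and CA3 cells 8 of 11 were open (adjusted p = 0.424, exact test), led by Pcp4 (5.45 and 2.43), Nectin3 (5.01 and 2.80) and Grik4 (4.24 and 2.58). Cacng5 and Coch each had a peak in a single replicate and Iyd in neither. For dentate granule cells 9 of 13 were open (adjusted p = 0.456, exact test), led by Rfx3 (6.88 and 4.22), C1ql2 (2.11 and 2.23) and Stxbp6 (2.19 and 1.57). The granule cell regulator gene Prox1 had a peak of height 1.70 in replicate 1 only, as did Lct and Tdo2, and Plk5 had none. For GABAergic interneurons 9 of 20 were open (adjusted p = 0.424, exact test), among them Adarb2 (1.62 and 1.36) and the neuropeptide gene Cck (0.941 and 1.34). The developmental regulators Dlx2, Lhx6 and Nkx2-1 had no promoter peak in either replicate. In the FDR 0.001 lists and among the top 50% of each replicate's peaks the interneuron list was below background (adjusted p = 0.00918 and 0.0327, exact tests), as it was against GC-matched lists (adjusted p = 0.0195, permutation test). In replicate 1 alone, however, 75% of interneuron genes had a promoter peak, against 63.4% of all genes. In replicate 2 the shares were 50% and 58.5%.

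Microglial and vascular promoters had a shared peak less often than those of other genes, and the astrocyte, oligodendrocyte and precursor lists did not pass the test. The tissue holds many cell types, so a promoter open only in a scarce type may give no peak. A missing peak therefore does not show that a promoter was closed in that cell type. Microglial genes were below background, with 3 of 16 open (adjusted p = 0.00739, exact test), among them Irf8 (2.90 and 1.52) and Sall1 (1.82 and 1.31). Csf1r and Cx3cr1 had a peak in replicate 1 only, and Aif1, C1qa and C1qb in neither. Vascular genes were also below, with 5 of 18 open (adjusted p = 0.0235, exact test), led by the glucose transporter gene Slc2a1 (4.59 and 2.31), Mfsd2a (1.79 and 1.39) and Rgs5 (0.588 and 0.538). Acta2, Kdr and Pdgfrb had a peak in replicate 1 only, the peaks at Flt1 did not overlap, and Cdh5, Cldn5 and Foxf2 had none. For astrocytes 6 of 15 were open (adjusted p = 0.252, exact test), led by the glutamine synthetase gene Glul (3.88 and 2.82), Sox9 (2.14 and 1.67) and the glutamate transporter gene Slc1a2 (2.19 and 1.59), and Gfap had no peak in either replicate. A promoter peak was present at 93.3% of astrocyte genes in replicate 1 and at 40% in replicate 2. For oligodendrocytes 6 of 16 were open (adjusted p = 0.177, exact test), led by Myrf (3.24 and 1.33), Mbp (1.98 and 1.14) and Olig1 (1.71 and 0.914), while Aspa and Mobp had no peak. For their precursors 4 of 9 were open (adjusted p = 0.533, exact test), led by Pdgfra (2.81 and 1.54), C1ql1 (1.95 and 1.14) and Vcan (1.43 and 0.678). Cacng4 and Cspg4 had a peak in replicate 1 only, and Gpr17, Matn4 and Neu4 had none. In replicate 1 alone the astrocyte list was above background (log2 odds 2.48, adjusted p = 0.025, exact test), against log2 odds of -0.96 for both replicates together. The vascular list did not pass in either replicate alone (adjusted p = 0.0737 in replicate 2 and 0.389 in replicate 1), for genes open in at least 1 replicate (0.258), with 50% reciprocal overlap (0.133) or without genes beside another start, an alternative chosen after seeing the data (0.121, exact tests), and the microglial list did not with reciprocal overlap (adjusted p = 0.0869, exact test). In the FDR 0.001 lists the oligodendrocyte and precursor lists were below background (adjusted p = 0.0038 and 0.0034, exact tests), as was the oligodendrocyte list with a promoter window of 200 bp (adjusted p = 0.0312, exact test). In replicate 1 alone, 75% of oligodendrocyte and 66.7% of precursor genes had a promoter peak, against 63.4% of all genes. The shares in replicate 2 were 37.5% and 44.4%, against 58.5%.

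Promoters of genes of other tissues were mostly closed. None of the 18 liver genes (Ahsg, Alb and Apoa2 among those without any peak) and none of the 15 muscle genes (Acta1, Ckm and Mb) was open, with adjusted p = 1.42e-06 and 1.45e-05 (exact tests). Apoa1, Nppa and Pygm had a peak in replicate 1 only. Of 17 blood and lymphoid genes 1 was open, with adjusted p = 5.25e-05 (exact test), and Alas2 and Cd3d were closed. Of 12 germ cell genes 1 was open, Dazl (2.29 and 1.43), with adjusted p = 0.00157 (exact test), and Acr, Ddx4 and Figla were closed. Of 12 epidermal genes 2 were open, the keratin gene Krt10 (3.88 and 2.19) and Grhl3 (0.471 and 0.635), with adjusted p = 0.0102 (exact test). Cdh1 and Flg had a peak in replicate 1 only, and Dsg3, Epcam and Ivl had none. Of 11 ependymal and choroid plexus genes 1 was open, the ciliogenesis regulator gene Foxj1 (7.36 and 3.23), with adjusted p = 0.00307 (exact test). Kl had a peak in replicate 1 only, and Aqp1, Ccdc153 and Clic6 had none. Of 17 markers of cerebellum, midbrain, hindbrain and hypothalamus 4 were open (adjusted p = 0.0102, exact test), among them Cbln3 (1.73 and 1.43), Agrp (0.941 and 1.37) and Tph2 (1.49 and 0.624). En2, Slc6a3 and Slc6a4 each had a peak in a single replicate, and Avp, Barhl1 and En1 had none. With 50% reciprocal overlap the ependymal, other brain region and epidermal lists did not pass (adjusted p = 0.0694, 0.0869 and 0.127, exact tests), nor did the epidermal list in replicate 1 alone (adjusted p = 0.0533, exact test). The other brain region and epidermal lists also did not pass with a promoter window of 2000 bp (adjusted p = 0.0698 and 0.107, exact tests) or for genes open in at least 1 replicate (adjusted p = 0.0976 and 0.052, exact tests). A start site of another protein-coding gene lay within 1000 bp at 2 of the 9 open members of these 7 lists (Cbln3 beside Khnyn, Agrp beside Ctcf) and at 3 of the 93 closed members (p = 0.0605, Fisher's exact test).

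Promoters of 3 clustered gene families were mostly closed. Of 39 Hox genes, which pattern the body axis, 1 was open, Hoxa7 (2.75 and 2.56), with adjusted p = 1.84e-12 (exact test), and Hoxa11 and Hoxa13 had no peak. Of 1092 olfactory receptor genes 9 were open, 0.824% against 60.1% of other genes, led by Olfr1392 (1.497 and 0.645), Olfr317 (0.914 and 0.613) and Olfr536 (0.92 and 0.452), while Olfr1, Olfr10 and Olfr1000 had no peak. Of 57 clustered protocadherins, cell-surface proteins of which each neuron uses a few, 3 were open, with adjusted p = 8.65e-16 (exact test): Pcdhgc3 (4.70 and 2.83), Pcdhac1 (3.26 and 2.52) and Pcdhac2 (1.01 and 1.58). Pcdha1 and Pcdha12 had no peak. A protocadherin promoter open in few neurons may likewise give no peak in whole tissue. A protocadherin promoter had a peak at 35.1% of genes in replicate 1 against 5.26% in replicate 2. For Hox genes these shares were 17.9% and 2.56%, and for olfactory receptor genes 3.21% and 1.37%.

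Distal sites were denser around excitatory neuron and immediate-early genes than around random genes of the same length. The excitatory neuron list had a median of 3.52 distal shared peaks per 100 kb (99.96th percentile of 10000 random lists, adjusted p = 0.024, permutation test). Tbr1, a regulator of glutamatergic neurons, had 10 distal sites (32.1 per 100 kb), Camk2a 7 (8.48) and Neurod6 3 (12.8). Of the 14 genes 10 had at least 1 site. The immediate-early list had a median of 3.46 (99.88th percentile, adjusted p = 0.0312, permutation test), and 9 of 16 genes had at least 1 site. Dusp1, over a longer span, had 5 sites (6.53 per 100 kb), Npas4 4 (15.4), Junb 3 (12.4) and Fos 2 (8.55). Of these genes Neurod6, Dusp1, Npas4, Junb and Fos were chosen after their values were seen. The next lists, microglia (median 2.30), oligodendrocyte (2.41) and housekeeping (2.06), did not pass (adjusted p = 0.146, 0.176 and 0.203, permutation tests), nor did any list not named here. The olfactory receptor and clustered protocadherin medians were 0, as was that of all genes. By mean density in the main lists, an alternative chosen after seeing the data, both families lay below every random list (adjusted p = 0.0016 each, permutation test, from the smallest p these permutations can give). Genes of the Pcdha cluster overlap and count the same 2 distal sites, while random lists were drawn gene by gene across the genome. Olfactory receptor genes also lie in clusters. The p-values of both families for distal density therefore treat neighbouring genes as separate draws and are descriptive only. In the FDR 0.001 lists the excitatory neuron and immediate-early medians were 0, as were those of their middle random lists, so the median could not rank them. By mean density there, chosen after seeing the data, the excitatory neuron and immediate-early lists did not pass (percentiles 98.6 and 99.8, adjusted p = 0.229 and 0.0528, permutation tests), and the olfactory receptor list was below while the clustered protocadherin list did not pass (percentiles 0 and 2.4, adjusted p = 0.0048 and 0.289, permutation tests). With 50% reciprocal overlap the excitatory neuron and immediate-early lists did not pass (percentiles 95.1 and 98.5). With a flank of 50 kb the excitatory list no longer passed (adjusted p = 0.112, permutation test), nor did the immediate-early list in replicate 1 alone (adjusted p = 0.0544, permutation test).

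Among genes of at least 10 kb, Tbr1 had the highest density of shared peaks. It lay on chromosome 2 (61802930 to 61814114, GRCm38), with 18 shared peaks, 57.7 per 100 kb of gene body and flanks. Shorter genes were not ranked. The median of the 14090 genes ranked was 3.30. Nfic, which encodes a nuclear factor I protein, followed with 44 peaks (55.4 per 100 kb; chromosome 10, 81396186 to 81455635), then Psd (48.5), Ubtf (45.5), B4galt5 (43.8), Iffo1 (41.0), Dvl2 (41.0), Gprin1 (39.2), Zfp512b (39.1) and Dph1 (38.7). The densest window of 100 kb, on chromosome 10 from 81400001, held 46 shared peaks, 10 of them at start sites, over Nfic, Celf5, Ncln and S1pr4. The next, on chromosome 10 from 69550001, held 34 inside Ank3 and none at a start site. A window on chromosome 2 from 167250001 held 32 over B4galt5, another on chromosome 11 from 69000001 held 29 over 7 genes including Per1 and Vamp2, and another on chromosome 13 from 23500001 held 28 over 15 histone genes. The other 5 windows held 22 to 24 shared peaks. They began at 54750001 on chromosome 13 (Sncb, Eif4e1b and Tspan17), 38200001 on chromosome 18 (Pcdh1, Dele1, Pcdh12 and Rnf14), 46300001 on chromosome 19 (8 genes including Psd and Sufu), 70750001 on chromosome 8 (8 genes including Rab3a and Kcnn1) and 30100001 on chromosome 17 (Zfand3). The median window held 1. The ranking depended on the replicate, since 5 of the 10 genes were among the 10 densest in replicate 2 alone (Tbr1, Nfic, Psd, Zfp512b and Dph1) and 1 (Psd) in replicate 1 alone. Of the 10 windows, 4 overlapped the 10 densest of replicate 2 and 3 those of replicate 1.

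The strongest distal shared peak lay in an annotated ribosomal RNA gene on chromosome 17 (39846781 to 39846900), with heights of 53.9 and 79.2; the nearest protein-coding gene was Esp38. The second lay in an exon of Lars2 on chromosome 9 (123461921 to 123462100; 36.7 and 40.5; nearest start, Limd1). The next 2 were intergenic, on chromosome 6 (49236421 to 49236620; 36.9 and 28.6) 21.5 kb from the nearest start, of Igf2bp3, and on chromosome 3 (5860361 to 5860530; 23.9 and 36.0) with Gm8797 as the nearest gene. The fifth lay within Zc3h7a on chromosome 16 (11144171 to 11144300), where the microRNA Gm23935 is also annotated (18.4 and 36.2; nearest start, Txndc11). The sixth overlapped an exon of Cers5 on chromosome 15 (99735661 to 99736060), with heights of 20.3 and 29.6 and Cox14 as the nearest start. The seventh lay in an exon of the pseudogene 2610005L07Rik on chromosome 8 (20424741 to 20424920), with heights of 21.04 and 14.1 and Gm15319 as the nearest protein-coding gene. The ninth lay in an intron of Gphn on chromosome 12 (78350881 to 78351080; 12.3 and 16.01) and the tenth in an intron of Jarid2 on chromosome 13 (44869561 to 44869700; 15.2 and 11.5). The eighth, on chromosome X (143483001 to 143483140) with Pak3 as the nearest gene, was strong in replicate 1 only, at 27.7 against 0.925. In 7 of these 10 peaks the median 31-base word occurred at 2 or more places in the assembly.

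Footprints were present in most shared peaks of both classes, and the 2 replicates differed in which class held more. In replicate 1, 80.9% of promoter peaks and 82.4% of distal peaks held a footprint, a difference of -1.49 percentage points. In replicate 2 the shares were 77.4% and 67.4%, a difference of 9.93 points. With a footprint of both replicates required they were 70.3% and 61.7%. The sign also depended on the peak list, since in replicate 2 the difference was -0.718 points with the FDR 0.001 lists and -3.54 among the top 50% of each replicate's peaks. At equal peak height, an alternative chosen after seeing the data, promoter minus distal shares were -11.2 points in replicate 1 and -12.9 in replicate 2. Of all footprints, 18.4% (95% interval 18.2 to 18.5) in replicate 1 overlapped a footprint of replicate 2, and 45.8% (45.5 to 46.1) of those in replicate 2 a footprint of replicate 1. Shuffled footprints gave 0.0995% and 0.225%, and within shared peaks the shares were 37.5% and 57.2%.

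Among footprints with room for a control segment, the binding sequences of 11 of the 24 motifs were enriched in both replicates. The NFI palindrome, bound by nuclear factor I proteins, was 6.67 times as frequent as in control segments in replicate 1 and 11 times in replicate 2, from 20 and 11 footprints against 3 and 1 control segments (adjusted p = 0.000901 and 0.0117, Fisher's exact test). The RFX palindrome was 4.02 and 3.12 times as frequent (adjusted p = 1.99e-19 and 3.83e-07, exact test). The CTCF motif was 2.59 and 8.25 times as frequent (adjusted p = 5.05e-13 and 1.89e-68, exact test), from 197 and 396 footprints. Without the need for a control segment, 2905 distal and 105 promoter footprints held it in replicate 1. In replicate 2 these numbers were 1275 and 73. Most CTCF footprints were thus left out of its ratio, which covers the remaining ones only. The E-box CAGATGG, bound by proneural basic helix-loop-helix factors such as the Neurod family, was 2.33 and 2.32 times as frequent (adjusted p = 3.99e-204 and 1.49e-75, exact test). It was present in 2.59% and 1.81% of the footprints with room for a control segment, which are not shares of all footprints. The other 7 were NRF1 (1.82 and 3.55), EGR (2.19 and 2.69), the cyclic AMP response element TGACGTCA (1.56 and 2.75), YY1 (1.79 and 2.73), SP/KLF (1.75 and 2.00), the single NFI site TTGGCA (1.49 and 1.19) and the E-box CAGCTG (1.47 and 1.27). The SOX motif was less frequent in footprints than in controls, at 0.794 and 0.80. AP-1 (1.06 and 0.884) and the liver factor motif HNF4 (1.04 and 1.12) passed in neither replicate. ETS passed in replicate 2 only (1.47, against 0.989 in replicate 1). MEF2 (1.43), ZNF143 (2.30), PU.1 (0.816) and GATA (0.478) passed in replicate 1 only, against 0.919, 2.00, 0.85 and 0.857 in replicate 2. REST also passed in replicate 1 only, from 6 footprints and no control segment (adjusted p = 0.0441, exact test), against 1 footprint and no control segment in replicate 2. NFY (1.07 and 1.42) passed in neither, nor did the paired SOX site, with 5 footprints against 8 control segments in replicate 1 and 0 against 1 in replicate 2, and HNF1 and P53 were found in no footprint. With control segments 50 bp away the NFI palindrome (ratio 2.75, adjusted p = 0.203, exact test) and the single NFI site (1.06, adjusted p = 0.15, exact test) did not pass in replicate 2. Without extension YY1 passed in neither replicate (adjusted p = 0.158 and 0.439, exact tests).

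**Figure D3:**
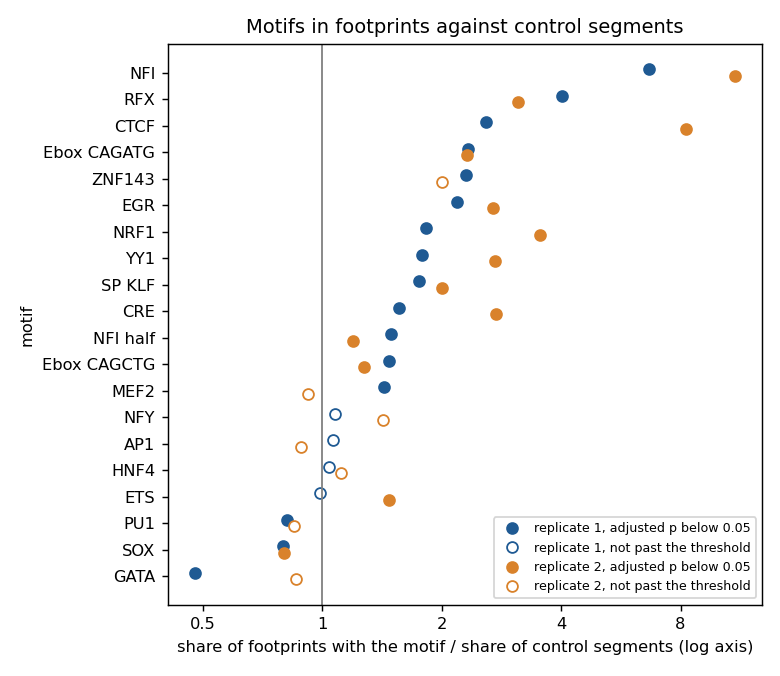
Ratio of the share of footprints holding a motif, among those with room for a control segment, to that of control segments in the same peaks (horizontal log axis), per motif and replicate, with filled points for an adjusted p below 0.05 and open points otherwise. RFX, CTCF and the E-box CAGATGG lie above 2 in both replicates, and SOX lies below 1 in both.

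Distal and promoter footprints held different motifs. CTCF was 11.1 times as frequent in distal as in promoter footprints in replicate 1 and 18.95 times in replicate 2, and the E-box CAGATGG 9.24 and 11.7 times. AP-1, bound by Fos and Jun proteins, was 4.95 times as frequent in distal footprints in both, the single NFI site 3.76 and 3.53 times, the E-box CAGCTG 2.62 and 2.21 times and SOX 2.10 and 2.07 times. Against control segments, however, AP-1 was not enriched in footprints (1.06 and 0.884), and SOX was less frequent (0.794 and 0.80). For these motifs the distal excess alone does not show binding. Promoter footprints were richer in 8 motifs in both replicates. Their ratios of distal to promoter shares were 0.0525 and 0.0721 for ETS, 0.0754 and 0.087 for SP/KLF, 0.104 and 0.152 for NRF1, 0.145 and 0.14 for the cyclic AMP response element, and 0.0209 and 0.0497 for YY1, with ZNF143, NFY and EGR also below 1. All 14 had an adjusted p of at most 1.34e-08 in each replicate (Fisher's exact test). Median GC content was 66.0% at promoter and 52.8% at distal shared peaks, and these ratios were not adjusted for it.

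The X chromosome of these male mice carried fewer and weaker sites than the autosomes. Shared peaks numbered 20.6 per Mb on autosomes, 7.87 on X and 0.238 on Y. The ratio of X to autosomes was 0.394 in replicate 1 and 0.411 in replicate 2, and 0.381 for shared peaks. Among autosomes, chromosome 11 was densest at 30.2 per Mb and chromosome 3 sparsest at 16.1. Of 948 X-linked genes 43.9% had an open promoter, against 58.2% of 20722 autosomal genes. Median heights at open promoters were 1.85 on X against 4.18 on autosomes in replicate 1, and 1.23 against 2.53 in replicate 2. Among the top 50% of each replicate's peaks by height the density ratio was 0.229.

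**Figure D4:**
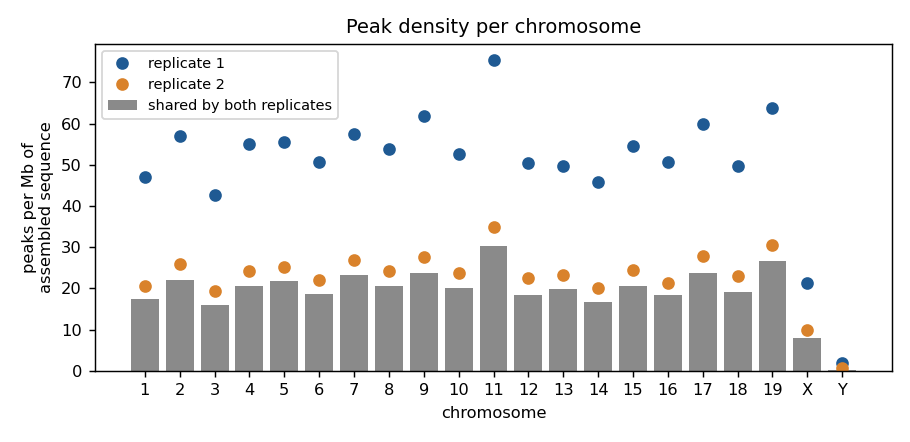
Peaks per Mb of assembled sequence (vertical axis) on each chromosome, with bars for shared peaks and points for each replicate. Chromosome 11 reached 30.2 shared peaks per Mb, X 7.87 and Y 0.238.

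The sequence passing the authors' FDR was longer in replicate 1 at each threshold. At an FDR of 0.05 intervals covered 37.0 Mb in replicate 1 and 20.2 Mb in replicate 2. At 0.01 they covered 28.3 and 14.8 Mb, and at 0.001 21.5 and 10.6 Mb.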

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

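These values lay in parts of the data that the comparisons of peaks did not use. They were chosen only after the data were seen, and no explanation was tested for them. In replicate 1, 17816 footprints (6.97%) lay outside all peaks of the longer list, as did 12163 (10.9%) in replicate 2. Of these, 98.2% and 97.8% overlapped an interval at an FDR of at most 0.05. Such intervals outside the peaks covered 13.2 Mb in replicate 1 and 7.18 Mb in replicate 2.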

How the results depend on the processing

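All alternatives except the mean distal density (also with the FDR 0.001 lists), equal deciles of height and exclusion of genes beside another start were fixed before the data were examined. The cause was not tested for any change given here. Of 264 promoter list values, 231 stayed on their side of the threshold, 12 of them with the other direction, 25 lost a call, 6 gained one and 2 reversed: astrocyte log2 odds ranged from -1.05 to 2.48 with a replicate left out and were 2.44 for genes open in at least 1 replicate. Lists above background numbered 2 with the FDR 0.001 lists, 2 with 50% reciprocal overlap and 3 against GC-matched lists, and lists below numbered 7 with reciprocal overlap. Of 216 distal values 203 stayed on their side, 13 of them with the other direction, not counting lists tied with the middle random list. With the FDR 0.001 lists 23 of the 24 list medians and their middle random lists were tied at 0, so percentiles there (49.2 and 49.9 for the excitatory neuron and immediate-early lists) say nothing of an excess. Distal lists above numbered 0 with the FDR 0.001 lists by median or mean, 0 with reciprocal overlap, 1 with a 50 kb flank and 1 to 2 with a replicate left out. Distal lists below numbered 1 with a 50 kb flank (olfactory receptors), 2 by mean density, 1 by mean density with the FDR 0.001 lists and 0 to 1 with a replicate left out (clustered protocadherins in replicate 1 alone). Of 159 motif values 147 stayed on their side, 11 of them with the other direction, and 3 reversed in replicate 1: MEF2 to 0.5 without extension, and PU1 to 1.11 and GATA to 1.14 in shared footprints. Peak overlap of replicates 1 and 2 was 35.7% and 87.5% with the FDR 0.001 lists, 43.5% and 93.3% in the top 50% of each list, 65.4% and 64.6% at equal length, and 24.3% and 53.9% with reciprocal overlap. Shared peaks numbered 28147, 28842 and 32100 with the FDR 0.001 lists, the top 50% and reciprocal overlap, and the height correlation was 0.765 in the top 50% of each list. Footprint overlap was 10.6% and 24.3% with reciprocal overlap, and 37.5% and 57.2% inside shared peaks. Values with a replicate left out are for the other replicate's peaks after overlapping ones were merged (131652 from 132685 and 58177 from 59880), so they differ slightly from those of unmerged peaks. The start-site share was 48.8% with the FDR 0.001 lists, 48.3% in the top 50% of each list and 17.8% to 31.1% with a replicate left out. Exons held 5.46%, 6.59% and 6.26% with the FDR 0.001, top-50% and equal-length lists and 7.38% to 7.40% with a replicate left out. Introns held 18.3% with the FDR 0.001 lists and 26.7% to 35.6% with a replicate left out, and intergenic sequence 27.4%, 24.8% (top 50%) and 34.8% to 39.3%. With a replicate left out, 1 to 5 of the 10 densest genes and 3 to 4 of the 10 windows stayed in the ranking. X over autosomes was 0.229 in the top 50% of each list, 0.290 at equal length, 0.344 with reciprocal overlap and 0.394 to 0.410 with a replicate left out, and autosomes held 23.6 to 53.4 peaks per Mb then. The promoter minus distal footprint difference in replicate 2 was -0.718 points with the FDR 0.001 lists, -3.54 in the top 50% of each list and -12.9 at equal height. For footprints of both replicates it was -2.03, -5.77 and -12.0, and in replicate 1 it was -11.2 at equal height. At an FDR of 0.001 the intervals covered 21.5 and 10.6 Mb. The shorter list of replicate 2 limits which weak sites can be shared. No paired comparison of groups was possible because there was 1 group.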

Other observations

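The tests on depth, signal over background, glial and vascular promoters (with the same test of other lists) and X copy number were chosen only after the values they bear on had been seen, and the GC test of glial promoters after the height-matched result but before its own. Both replicates belong to 1 group, so the design gave no biological difference between them to test, and cell composition was tested only from marker lists. Comparisons of height between replicates assume that heights were scaled by depth, which was inferred.

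Replicate 2 had fewer peaks than replicate 1 by a factor of 2.22. Lower depth alone would leave depth-scaled heights equal at strong promoters, but at the 15 housekeeping promoters the median log2 ratio of replicate 2 to replicate 1 was -0.97 (95% interval over genes -1.21 to -0.88, all 15 lower), which argues against depth as the whole cause, while signal over background was not measured and stays open. Of 46 glial and vascular promoters with a peak in replicate 1, 54.3% had a peak in replicate 2, below the central 95% of height-matched sets of other promoters (60.9% to 82.6%), against 83.7% of 92 neuronal promoters (79.3% to 92.4%); matching on GC content as well left the glial and vascular number at the 0.71 percentile, which argues against GC content as the whole cause. By list the percentiles among sets matched on height and GC content were 0.56 for astrocytes (6 of 14), 7.62 for oligodendrocytes (6 of 12), 17.2 for microglia (3 of 5), 27.2 for precursors (4 of 6) and 71.3 for vascular cells (6 of 9), but of 13 other lists 2 also lay below the 2.5 percentile, Hox genes (1 of 7, 0.055) and clustered protocadherins (3 of 20, below every set), so a smaller share of glial nuclei in replicate 2 cannot be told apart from a loss of peaks that was not confined to glial genes. At promoters open in both replicates, the neuronal minus glial and vascular log2 ratio was 0.031 (-0.23 to 0.41, permutation p = 0.745), inside the bound of 0.5 that had been set beforehand as evidence against a difference in cell composition; this was not taken as decisive, by a coverage requirement added after the result was seen, because that test holds only 52.2% of the 46 glial and vascular promoters with any peak and leaves out those without a peak in replicate 2.

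The strongest distal peaks lay mostly in sequence that occurs more than once in the assembly. In 7 of the 10 the median 31-base word lay at 2 or more places, against 1 of 100 random distal shared peaks (p = 2.94e-08, two-sided Fisher's exact test), and at the peak nearest Gm8797 the median was 7 places. Reads gathered from several copies may account for the heights at those 7, but how reads with several matches were placed is not given in the sources used here. In Cers5 no such word occurred at a further place, while near Pak3 and in Jarid2 the median was 1 place but 33.6% and 37.3% of words lay at 2 or more, so the heights of these 3 stay open, including 27.7 against 0.925 near Pak3.

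Open promoters on X had lower heights than autosomal promoters. The ratio of medians was 0.487 in replicate 2 (95% interval over genes 0.453 to 0.521) and 0.442 in replicate 1 (0.411 to 0.487). Over all promoters, 1 X copy per male cell against 2 of each autosome predicts 0.5. The interval holds 0.5 in replicate 2 and lies below it in replicate 1. The ratios cover only open promoters, 43.9% of those on X and 58.2% on autosomes. For such a selected set 0.5 is not an exact prediction, so the intervals cannot decide on copy number. Autosomal promoters matched to the GC content of X promoters gave 0.464 (0.415 to 0.531) and 0.509 (0.463 to 0.560) in replicates 1 and 2, which argues against GC content as the whole cause. Copy number, alone or with lower activity of X-linked genes, which was not tested, stays open.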
